A study of Mus musculus with 10 samples.

How the data were processed

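Poly(A) messenger RNA of 10 libraries was sequenced, per the labels' protocols, from sorted cells of C57BL/6 mice aged 8 weeks. Each of the 5 groups had 2 libraries: MHCII+ cells of the colon and of the spleen, and CD11c+, CD11b+CD11c+ and CD11b+ cells of the colon. The MHCII+ libraries and the subset libraries carry separate runs of library numbers, called sets here. The abbreviations of the sample labels were read through the series title. Both splenic titles carry the same replicate number, so these libraries were numbered 1 and 2 in the order of their listing.

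The authors deposited kallisto estimated counts, effective lengths and TPM values (scaled by effective length to a common total) for each transcript, per the file headers. kallisto 0.44.0, sleuth and the mm10 assembly are named in the submitters' processing notes, and the target sequences are not stated. Of the deposited lengths, 88.9% were multiples of 3, 93.4% equalled the annotated coding length of the transcript and 99.8% lay within 3 bases of it, so lengths are called coding lengths here. Of 66760 transcripts, 65747 were matched by identifier to 22607 genes of GENCODE release M21 and 1013 were not matched and were left out of the comparisons. Genes, coordinates and symbols are those of that release. Reads of near-identical genes (immunoglobulin segments, haemoglobin, Cd209 and Oas family genes) were split by kallisto, and their counts are uncertain. One listed gene, Ifi30, was not found in the annotation.

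Estimated counts were summed per gene, rounded and tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default filter on low counts (15074 genes kept) and 1 mean per group. All 10 libraries entered 1 quasi-likelihood fit, with 5 residual degrees of freedom, because each group had only 2. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05, and the SE of a log2 fold change is its size divided by the square root of the F statistic. A signature gene of a subset was higher than both other colonic subsets, with the larger of both p-values adjusted. The 33 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry. At the preset correlation 19, 24, 15 and 20 lists were called in the 4 comparisons, in the order of the results, and 0 with an estimated correlation, where the smallest adjusted p-values were 0.218, 0.31, 0.19 and 0.302. In the results a list is named called or not by camera at the preset correlation, and fry differed for some lists. In colonic against splenic MHCII+ cells, fry passed lists that camera did not, such as red pulp macrophages (fry adjusted p = 0.027) and T cells (fry adjusted p = 0.011). In CD11b+CD11c+ against CD11b+ cells, lists that camera called did not pass fry, such as epithelium (fry adjusted p = 0.263) and plasma cells (fry adjusted p = 0.365). Overlap with the signatures was tested with Fisher's exact test over 15074 genes. Tables were handled with Python 3.11.15 and pandas 2.3.3. The tests, gene lists, rule for named genes and 8 of the alternatives were chosen before the data were examined.

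Named genes were the sorting markers, the 8 genes with the smallest p in each direction, and up to 4 members with the smallest p of each list described. The 8 had at least a 2-fold change, 10 CPM in the higher group and no overlap between the libraries of both groups, and segments of antigen receptors and unnamed gene models were left out. Not every gene that this rule takes is printed. With 2 libraries against 2, chance alone gives no overlap in a given direction in 1 of 6 cases. One clone-named gene model with a digit after its ending was also left out, a reading of this rule made after the list was seen, and Prkd2 took its place. Genes at 3 counts or fewer in a group are given no fold change.

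Totals ranged from 12806139 to 41769042 estimated counts per library, and 3 counts of a total give the level that a count of 0 allows. Intervals and such limits cover counting error only. On simulated counts for 15074 genes with 200 changed, the test recovered 48% of genes changed 2-fold and 82% of those changed 4-fold in colonic against splenic MHCII+ cells. These shares were 48% and 75% in CD11b+ against CD11c+ cells, 45% and 83% in CD11b+CD11c+ against CD11b+ cells, and 50% and 81% in CD11b+CD11c+ against CD11c+ cells, with 5, 5, 4 and 2 false calls. The simulated CD11b+ signature recovered 33 of 50 genes changed 4-fold with 1 false call. All other genes were drawn from 1 mean over all libraries. The simulation therefore says nothing on errors from the far wider changes, or from scaling, in the real comparisons.

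The alternatives were DESeq2 (1.42.0) size factors in the same fit, no filter, DESeq2's Wald test, limma on log2(TPM + 1) and on log2(TPM + 0.1), an effective length offset, fits on the libraries of a comparison's own set, a replicate block, and each library left out in turn. A group left with 1 library is then assumed to vary like the others. Fits without immunoglobulin and mitochondrial genes, and the overlap among genes of at least 10 mean CPM, were added after seeing the data.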

Results

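Messenger RNA was sequenced from antigen-presenting cells of C57BL/6 mice aged 8 weeks. Cells bearing MHC class II, the molecules that display peptides to CD4 T cells, came from the colon and from the spleen. Colonic mononuclear phagocytes and dendritic cells were separated into 3 further subsets by 2 integrins, CD11b (encoded by Itgam) and CD11c (encoded by Itgax). These subsets are called CD11c+, CD11b+CD11c+ and CD11b+ cells. Each of the 5 groups had 2 libraries, and estimated counts per library ranged from 12806139 to 41769042. A count of 0 allowed a level of up to 0.0723 to 0.236 CPM (counts scaled to a common total), which covers counting error only. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples. Replicates differed beyond sampling noise in all 5 groups, with chi-square values per degree of freedom from 11.4 to 41 over genes. Levels are given as mean ± SD CPM (n = 2 libraries per group), fold changes as log2 ± SE, and p-values are adjusted unless named otherwise.

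The first principal component held 63.4% of the variance of the 1000 most variable genes and set the 2 splenic libraries apart from the 8 colonic ones. The second held 16.9% and placed the colonic libraries from CD11c+ cells (53.04 and 47.45) to colonic MHCII+ cells (-42.63 and -48.38). The colonic MHCII+ libraries belong to another numbered set than the subset libraries, so their place against the subsets also crosses sets. Of the sorting markers, Itgam (chromosome 7, 128062640 to 128118491 in the mm10 assembly) stood at 34.2 ± 10.3 CPM in CD11c+ cells, 814 ± 86.9 in CD11b+CD11c+ cells and 763 ± 4.17 in CD11b+ cells. Itgax stood at 892 ± 107, 794 ± 81.1 and 539 ± 50.3 CPM in the same order, so its transcript was also present in the CD11b+ libraries. H2-Ab1, which encodes an MHC class II beta chain, was abundant in every group, from 4350 ± 1070 CPM in CD11b+ cells to 7540 ± 896 in CD11c+ cells.

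**Figure D1:**
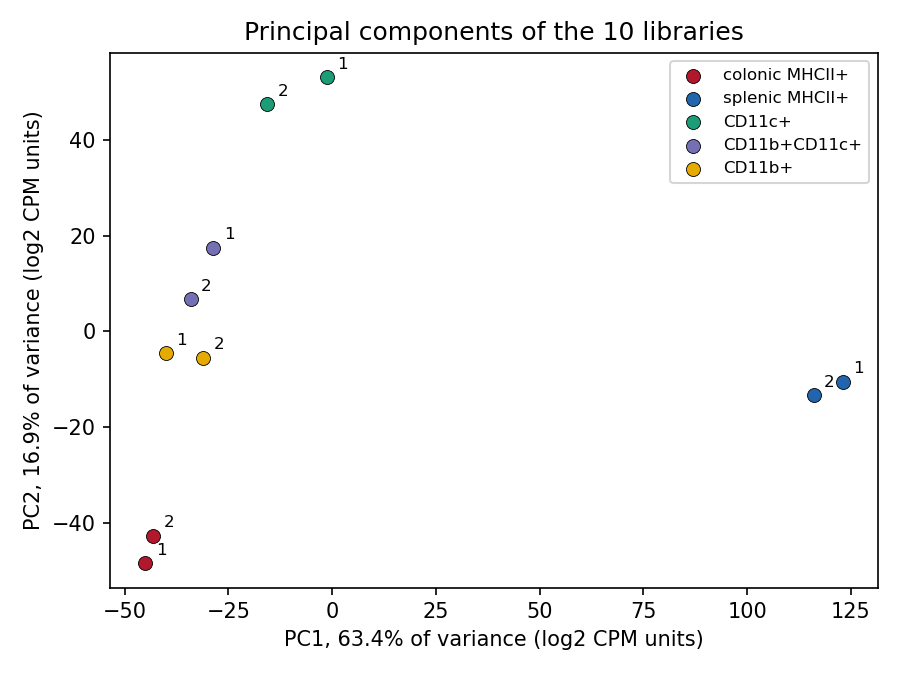
Principal components 1 and 2 (log2 CPM units) of the 10 libraries, over the 1000 most variable genes; each point is a library, coloured by group and numbered by replicate. Splenic libraries lie at 116.01 and 123.03 on the first component and all colonic libraries below 0.

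**Figure D2:**
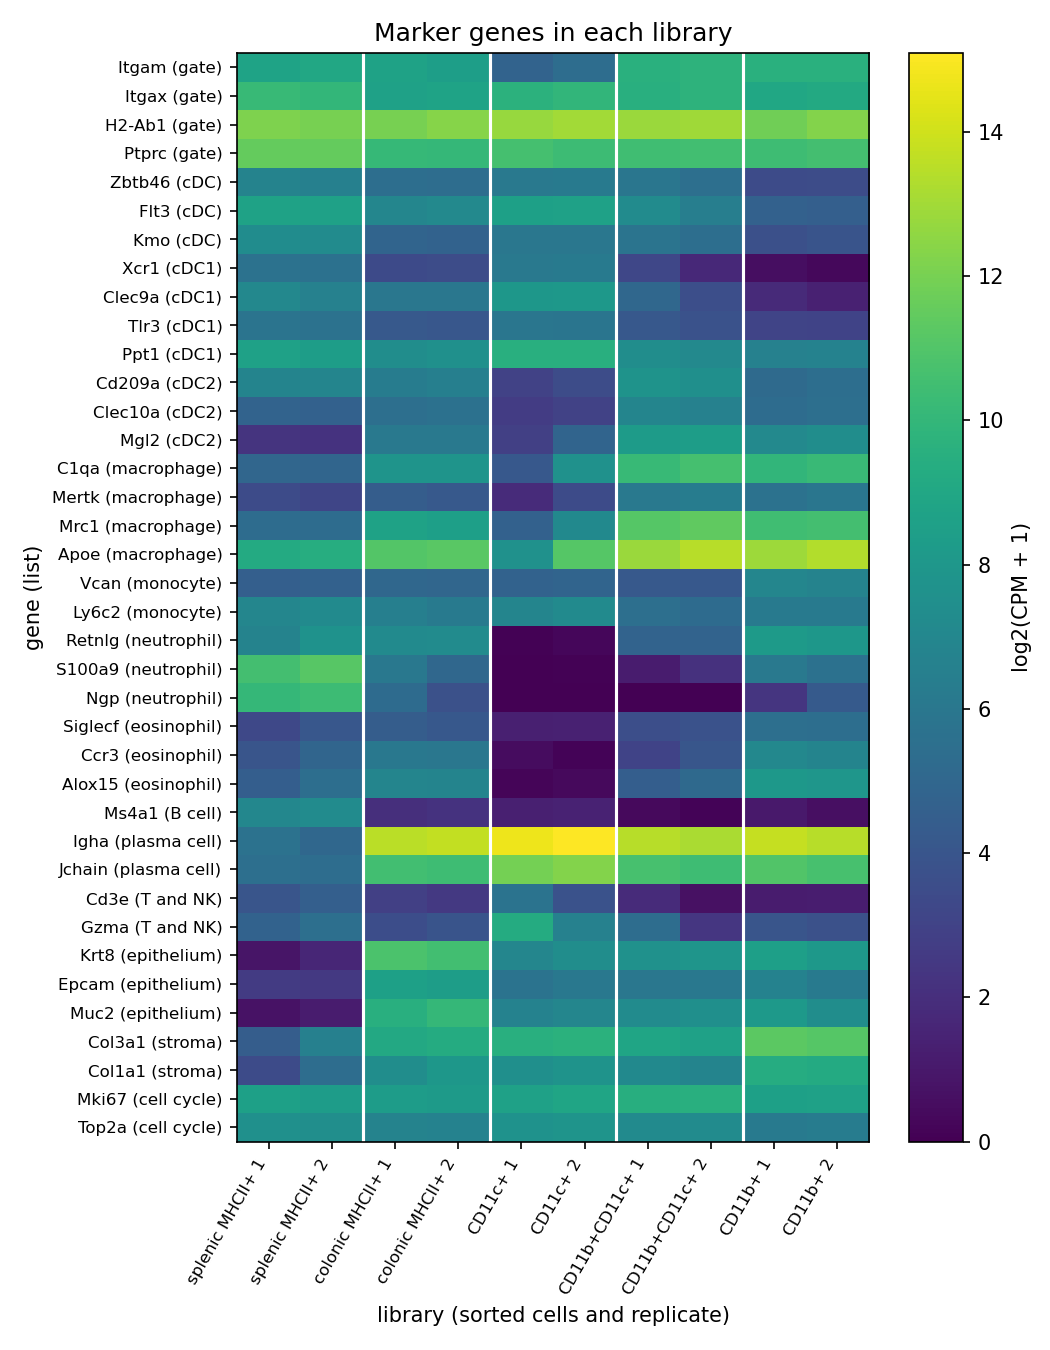
Levels of marker genes, as log2(CPM + 1), in each of the 10 libraries (columns), with the list each gene belongs to in brackets. Igha is high in the 8 colonic libraries, Ms4a1 in the 2 splenic ones, and the 2 CD11c+ libraries differ in macrophage genes.

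The comparison of colonic with splenic MHCII+ cells asks which genes mark antigen-presenting cells of the gut. In colonic cells, chemokine genes, macrophage genes and genes for immune-regulating factors were higher, and the genes of B cells and of the type I interferon response were lower. Of 19 chemokine genes, 15 rose and 1 fell, among them the membrane-bound chemokine gene Cxcl16 (10.1-fold, log2 3.33 ± 0.25, adjusted p = 7.43e-06), and Ccl17 (64.5-fold) and Ccl22 (18.6-fold), whose products bind CCR4 on T cells. The chemokine list was called as a whole (camera adjusted p = 4.08e-04, adjusted p = 0.495 with an estimated correlation). Of 23 macrophage genes, 16 rose, 2 fell and 5 did not pass the test (camera adjusted p = 0.00641, adjusted p = 0.599 with an estimated correlation). Examples were Dab2 (log2 6.06 ± 0.37, adjusted p = 2.22e-06), the folate receptor gene Folr2 (log2 4.38 ± 0.44) and the scavenger receptor gene Stab1 (log2 5.69 ± 0.67). Genes of splenic red pulp macrophages, which recycle iron, went the other way, with 6 of 10 lower and none higher, and this list was not called (camera adjusted p = 0.0554, adjusted p = 0.581 with an estimated correlation). Ccl17 had log2 changes of 5.25 without splenic MHCII+ replicate 1 and 7.23 without splenic MHCII+ replicate 2.

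In the list of retinoic acid, TGF-beta and tolerance genes, 10 of 16 rose and 1 fell (camera adjusted p = 0.0276, adjusted p = 0.428 with an estimated correlation). Aldh1a2, which encodes an enzyme that makes retinoic acid, stood 7.28-fold higher in colonic cells (22.5 ± 2 against 3.08 ± 0.202 CPM, adjusted p = 1.11e-06). Lrrc32, which encodes a protein that holds latent TGF-beta at the cell surface, rose by a log2 change of 2.96 ± 0.20, and Thbs1, an activator of TGF-beta, by 5.64 ± 0.48. Inflammatory cytokine genes went the same way, with 9 of 16 higher and 2 lower (camera adjusted p = 0.0201, adjusted p = 0.581 with an estimated correlation), including Il6 (log2 5.10 ± 0.27) and Tnfsf9, a costimulatory ligand gene (log2 1.95 ± 0.15). Of 18 lysosome genes, 12 rose and 2 fell, such as the cathepsin genes Ctsk (log2 2.69 ± 0.22) and Ctsd (log2 1.29 ± 0.11) (camera adjusted p = 0.0433, adjusted p = 0.646 with an estimated correlation).

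All 15 B cell genes were lower in colonic cells (camera adjusted p = 3.16e-07, adjusted p = 0.218 with an estimated correlation). Ms4a1, which encodes CD20, stood at 3.37 ± 0.281 against 139 ± 20.3 CPM (log2 -5.37 ± 0.23, adjusted p = 4.88e-07), and Cr2, a complement receptor gene of B cells, had a log2 change of -5.31 ± 0.28. Of 17 interferon-stimulated genes, 16 fell and 1 did not pass (camera adjusted p = 2.19e-05, adjusted p = 0.387 with an estimated correlation), among them Irf7 (log2 -1.69 ± 0.12, adjusted p = 4.51e-06) and Mx1 (log2 -1.47 ± 0.12). Neutrophil genes fell in 12 of 14 cases (camera adjusted p = 1.99e-04, adjusted p = 0.428 with an estimated correlation), with Lcn2 at 11.8 ± 5.25 CPM in colonic and 425 ± 83.4 in splenic cells and S100a8 at 29 ± 9.9 and 1330 ± 433. Of the genes of type 1 conventional dendritic cells (cDC1), which present antigen to CD8 T cells, 10 of 12 fell (camera adjusted p = 0.00641, adjusted p = 0.526 with an estimated correlation), including Tlr3, a sensor of double-stranded RNA (log2 -1.65 ± 0.14), and Irf8 (log2 -1.25 ± 0.12). Itgae, which encodes the CD103 chain of gut dendritic cells, rose instead (log2 3.18 ± 0.40). The general dendritic cell list had 8 lower and 2 higher of 10 (camera adjusted p = 0.0196, adjusted p = 0.433 with an estimated correlation), with Kmo at log2 -2.55 ± 0.13 and Cd80, a costimulatory ligand, at 2.39 ± 0.13.

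Of 11 tested genes of class II presentation, 5 fell and none rose (camera adjusted p = 0.0433, adjusted p = 0.582 with an estimated correlation). Ciita, the master regulator of class II genes, fell 12.2-fold (adjusted p = 4.88e-07) and H2-Oa 5.5-fold. H2-Ab1 (log2 0.08 ± 0.19), H2-Aa (log2 0.10 ± 0.18) and Cd74 (log2 -0.12 ± 0.19) did not pass the test. The genes with the smallest p-values among those higher in colonic cells were Ramp3, Gprc5a, Maoa, Lurap1l, Acta1, Dsp, Shroom3 and Guca2a. The colonic libraries also carried epithelial transcripts, such as Krt8 at 1780 and 1500 CPM against 0.811 and 2.03 in the splenic ones. These genes are therefore not shown to mark antigen-presenting cells, and which cells express them was not tested. Ramp3, a partner of calcitonin family receptors, stood at 118 ± 0.825 against 0.576 ± 0.103 CPM (log2 7.68 ± 0.14, adjusted p = 3.89e-08). Among those lower were Ikzf1, a transcription factor gene of lymphoid and myeloid cells (6.39-fold, log2 -2.68 ± 0.10), Ifi209 (6.56-fold), Clec4a4 (25.8-fold), Arid1a, Myo1f, Sp100, Tmem131l and Prkd2.

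Markers of other cells moved with the tissue. All 15 epithelial genes rose (camera adjusted p = 5.45e-10, adjusted p = 0.387 with an estimated correlation), such as Vil1 (log2 9.96 ± 0.30), Tff3 (68.4 ± 13.3 against 0.0642 ± 0.0289 CPM) and Epcam (363 ± 35.4 against 4.93 ± 0.466 CPM). Stromal and endothelial genes rose in 9 of 12 and fell in 3, and the list was not called (camera adjusted p = 0.0939, adjusted p = 0.591 with an estimated correlation), with Col3a1 at log2 3.32 ± 0.57, Sparc at 1.92 ± 0.20 and Pecam1 at -2.23 ± 0.15. Of 11 plasma cell genes 10 rose and 1 fell (camera adjusted p = 1.99e-04, adjusted p = 0.433 with an estimated correlation), with Sdc1 at log2 4.97 ± 0.19, Jchain at 5.04 ± 0.20 and Igha, the heavy chain of immunoglobulin A, at 12400 ± 1070 against 40.9 ± 13 CPM. T cell genes fell in 8 of 14 and rose in 1 (camera adjusted p = 0.0518, adjusted p = 0.582 with an estimated correlation). NK cell and innate lymphoid genes rose in 6 of 14 and fell in 1 (camera adjusted p = 0.178, adjusted p = 0.663 with an estimated correlation), and neither list was called. Ptprc, which encodes the pan-leukocyte protein CD45, was 2.71-fold lower in colonic cells (adjusted p = 1.01e-05). The interferon-stimulated and cDC1 lists had median log2 changes of -1.82 and -1.26. Whether these lists fell beyond a lower share of leukocyte RNA in the colonic libraries was not tested. In all, 5010 of 15074 genes were higher and 4633 lower in colonic cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 3466 and 2220 changed at least 2-fold. Adjusted over the list alone, the cDC1 list had 11 lower and the inflammatory list 10 higher, and the other lists of this comparison named above kept their counts. Col3a1 had log2 changes of 2.60 without splenic MHCII+ replicate 1 and 4.82 without splenic MHCII+ replicate 2.

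The comparison of CD11b+ with CD11c+ colonic cells asks what separates phagocytes marked by one integrin from those marked by the other. Macrophage, lysosome and complement genes were higher in CD11b+ cells, and genes of cDC1, of T and natural killer (NK) cells and of cell division were lower. All 23 macrophage genes rose (camera adjusted p = 1.76e-09, adjusted p = 0.335 with an estimated correlation). Maf, a transcription factor gene of resident macrophages, stood at 56.8 ± 2.33 against 6.92 ± 0.0955 CPM (log2 3.03 ± 0.18, adjusted p = 9.45e-06), Cd163, the haemoglobin scavenger receptor gene, at log2 4.82 ± 0.41, and Folr2 at 4.81 ± 0.42. All 18 lysosome genes rose (camera adjusted p = 7.19e-09, adjusted p = 0.31 with an estimated correlation), with Ctsd 8.01-fold and Lamp2 3.56-fold higher. All 13 complement genes rose (camera adjusted p = 4.2e-07, adjusted p = 0.31 with an estimated correlation), including C3 (log2 2.72 ± 0.12) and Itgam itself, 22.4-fold higher (adjusted p = 5.32e-06). Itgam encodes the marker that sets CD11c+ cells apart from both other subsets, so its rise follows from the sort. The complement and macrophage lists share C1qa, C1qb and C1qc, and the macrophage and lysosome lists share Cd63. These lists are therefore not independent results. Cd163 and Folr2 had log2 changes of 4.20 and 4.10 without CD11c+ replicate 1 and 5.75 and 5.83 without CD11c+ replicate 2.

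Chemokine genes were higher in 15 of 19 cases and lower in 2 (camera adjusted p = 1.72e-04, adjusted p = 0.335 with an estimated correlation), led by Ccl6 (30.2-fold) and Ccl9 (58.8-fold). Ccl24 stood at 18.7 ± 1.79 against 0.185 ± 0.262 CPM, and CD11c+ replicate 1 held no count of it. Of 22 pattern recognition genes 18 rose and 2 fell (camera adjusted p = 1.73e-05, adjusted p = 0.335 with an estimated correlation). Tlr4, the endotoxin receptor gene, rose by 2.96 ± 0.16 on the log2 scale, while Tlr3 (-2.98 ± 0.15) and Tlr11 (-5.48 ± 0.23) fell. Monocyte genes rose in 9 of 12 cases and fell in 1 (camera adjusted p = 5.63e-05, adjusted p = 0.31 with an estimated correlation), such as Chil3 (39.1 ± 0.76 against 0.112 ± 0.103 CPM) and Ms4a4c (log2 3.47 ± 0.16). Inflammatory cytokine genes rose in 11 of 16 and fell in 1 (camera adjusted p = 0.00149, adjusted p = 0.347 with an estimated correlation), with Tnfsf9 at log2 2.29 ± 0.15 and Il6 at 2.07 ± 0.24. Immediate early and stress genes, which also respond to tissue digestion, rose with them in 13 of 18 (camera adjusted p = 1.84e-04, adjusted p = 0.347 with an estimated correlation), with Egr2 at log2 2.62 ± 0.17 and Ier3 at 3.64 ± 0.35. The tolerance list had 8 of 16 higher and 2 lower (camera adjusted p = 0.00853, adjusted p = 0.31 with an estimated correlation). Of the interferon-stimulated genes 12 of 17 rose and 2 fell (camera adjusted p = 6.08e-04, adjusted p = 0.31 with an estimated correlation), such as Oas1a (log2 2.77 ± 0.16) and Oasl2 (log2 3.33 ± 0.26). Ccl9 had log2 changes of 5.16 without CD11c+ replicate 1 and 6.96 without CD11c+ replicate 2. Ier3 had a log2 change of 4.36 without CD11c+ replicate 2.

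All 12 cDC1 genes were lower in CD11b+ cells (camera adjusted p = 7.19e-09, adjusted p = 0.31 with an estimated correlation). Ppt1 stood at 100 ± 5.65 against 726 ± 4.53 CPM (adjusted p = 4.78e-06) and Tlr3 at 7.45 ± 0.382 against 58.6 ± 0.484, and Naaa was 9.13-fold lower. The general dendritic cell list had 8 of 10 lower and 2 higher (camera adjusted p = 0.00363, adjusted p = 0.31 with an estimated correlation), with Zbtb46, a transcription factor of conventional dendritic cells, at 10.3 ± 0.375 against 69.1 ± 1.72 CPM and Kmo, a kynurenine pathway gene, at log2 -2.27 ± 0.14. Class II presentation genes fell in 8 of 11 cases and rose in 1 (camera adjusted p = 6.97e-04, adjusted p = 0.336 with an estimated correlation), such as H2-DMb2 (log2 -2.10 ± 0.14) and H2-Ob (log2 -3.08 ± 0.21). Genes of type 2 conventional dendritic cells (cDC2) went the other way, with 7 of 10 higher and 1 lower (camera adjusted p = 0.00505, adjusted p = 0.31 with an estimated correlation), such as the lectin genes Clec10a (log2 2.75 ± 0.15) and Cd209a (log2 2.23 ± 0.19). Cell cycle genes fell in 14 of 15 cases (camera adjusted p = 3.43e-07, adjusted p = 0.31 with an estimated correlation), with Top2a 2.81-fold and Mcm6 2.65-fold lower. Subunits and transporters of class I presentation fell too, 6 of 13 against 2 higher (camera adjusted p = 0.00876, adjusted p = 0.31 with an estimated correlation), such as the immunoproteasome genes Psmb9 (log2 -2.39 ± 0.16) and Psmb8 (log2 -1.60 ± 0.11).

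The smallest p-values among higher genes included those of Gda (21.8-fold), Ccl6, Rab44, Serpinb2, Cd300lf, Nfe2 and Ctsd, and among lower genes those of Tlr11, Palb2, Rnase6, Ppt1, Zdhhc23, Tlr3, the checkpoint receptor gene Havcr2 (4.97-fold) and Itga3. Other cell types moved with these groups. Granulocyte genes were higher in CD11b+ cells, in 13 of 14 neutrophil genes (camera adjusted p = 1.83e-08, adjusted p = 0.31 with an estimated correlation) and 6 of 9 eosinophil genes (camera adjusted p = 0.00131, adjusted p = 0.31 with an estimated correlation), with Retnlg at 274 ± 29.3 against 0.132 ± 0.0752 CPM and Alox15 at 256 ± 10.8 against 0.233 ± 0.107. Levels in CD11b+ replicates 1 and 2 differed widely between neutrophil genes, with Csf3r at 230 and 210 CPM, S100a8 at 21 and 20.7 and Ly6g at 0.394 and 1.18. While Csf3r and S100a8 were close between the replicates, Ngp (3.94 and 18.1 CPM) and Ltf (5.91 and 19.9) were not. Stromal genes rose in 9 of 12 (camera adjusted p = 0.00428, adjusted p = 0.347 with an estimated correlation), with Sparc at 245 ± 14.8 against 82.2 ± 5.26 CPM, and epithelial genes in 11 of 15 (camera adjusted p = 0.00204, adjusted p = 0.388 with an estimated correlation), with Tff3 at log2 2.01 ± 0.20. T cell genes fell in 13 of 14 with 1 higher (camera adjusted p = 3.43e-05, adjusted p = 0.31 with an estimated correlation), NK cell and innate lymphoid genes in 10 of 14 with 2 higher (camera adjusted p = 0.0067, adjusted p = 0.388 with an estimated correlation) and plasma cell genes in 9 of 11 with 1 higher (camera adjusted p = 0.00876, adjusted p = 0.388 with an estimated correlation). Cd6 stood at log2 -2.12 ± 0.24, Klrk1 at -3.22 ± 0.25 and Jchain at -1.27 ± 0.17.

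Of the sorting markers, Itgax had a log2 change of -0.73 ± 0.13 (adjusted p = 0.00195), with H2-Ab1 at -0.79 ± 0.19, H2-Aa at -0.46 ± 0.18, Cd74 at -0.36 ± 0.19 and Ptprc at -0.02 ± 0.11; H2-Aa, Cd74 and Ptprc did not pass the test. In total 3707 genes were higher and 3616 lower in CD11b+ cells (edgeR, 15074 tested). The 2 CD11c+ libraries differed from each other. Cd163 stood at 7.19 CPM in replicate 1 and 20.7 in replicate 2, and Folr2 at 1.78 and 5.81. Lymphocyte genes went the other way. In replicate 2, 12 of 14 T cell genes and 13 of 14 NK cell and innate lymphoid genes were lower than in replicate 1 (median log2 ratios of -1.33 and -0.77), such as Lck at 140 and 54.1 CPM. Without CD11c+ replicate 1, the higher genes numbered 2429 and the lower 2724, and without replicate 2 they numbered 3176 and 3249. Adjusted over the list alone, 9 class II genes fell, 12 epithelial, 11 stromal and 9 tolerance genes rose, and the other lists named here kept their counts. H2-Ab1 did not pass the test without CD11b+ replicate 1 (log2 -0.56). H2-Aa passed the test without CD11b+ replicate 2 (log2 -0.72). Cd74 passed the test without CD11b+ replicate 2 (log2 -0.62).

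The comparison of CD11b+CD11c+ with CD11b+ colonic cells sets side by side cells that share CD11b and were sorted apart by CD11c. Dendritic cell genes and genes of class II presentation were higher in CD11b+CD11c+ cells, and granulocyte, monocyte and stromal genes were lower. Of 23 macrophage genes, 22 did not pass the test, which does not show that their levels were equal. Of the general dendritic cell list 5 of 10 genes rose and none fell (camera adjusted p = 1.1e-06, adjusted p = 0.19 with an estimated correlation). Zbtb46 stood at 51.8 ± 10.6 against 10.3 ± 0.375 CPM (5.04-fold, log2 2.33 ± 0.15, adjusted p = 2.19e-04), Kmo 3.73-fold and Flt3 5.11-fold higher. Of 12 cDC1 genes 10 rose (camera adjusted p = 2.59e-07, adjusted p = 0.259 with an estimated correlation), such as Naaa (log2 1.48 ± 0.16) and Wdfy4, needed for cross-presentation (log2 1.77 ± 0.21). The 2 CD11b+CD11c+ libraries differed in this list, with Clec9a at 32.6 CPM in replicate 1 and 11.5 in replicate 2. Itgae stood at 160 and 70 CPM in the same order, while Cadm1 went the other way (21.6 and 38.1). The cDC2 list had 4 of 10 higher (camera adjusted p = 0.00463, adjusted p = 0.259 with an estimated correlation), with the lectin genes Cd209a (log2 2.33 ± 0.18, adjusted p = 3.63e-04) and Clec10a (log2 1.34 ± 0.14).

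Genes of mature, migrating dendritic cells rose in 6 of 15 cases (camera adjusted p = 4.24e-05, adjusted p = 0.19 with an estimated correlation), among them Traf1 (2.36-fold) and Ccr7, the receptor that guides them to lymph nodes (5.22-fold, adjusted p = 5.69e-04). Class II presentation genes rose in 7 of 11 cases (camera adjusted p = 2.59e-07, adjusted p = 0.259 with an estimated correlation), such as H2-DMb2 (log2 2.31 ± 0.14) and H2-Oa (log2 1.89 ± 0.19). Cell cycle genes rose in 9 of 15 (camera adjusted p = 6.7e-08, adjusted p = 0.19 with an estimated correlation), with Top2a at log2 0.95 ± 0.09 and Mki67 at 0.92 ± 0.11. Aldh1a2 stood 2.59-fold higher (adjusted p = 9.27e-04), although the tolerance list was not called, with 3 higher and 1 lower of 16, among them Pdcd1lg2 at log2 1.92 ± 0.33, a median log2 change of 0.08 and a camera direction towards lower (camera adjusted p = 0.828, adjusted p = 0.903 with an estimated correlation). Macrophage genes showed 1 call, Maf at log2 0.60 ± 0.16, and the list was not called (camera adjusted p = 0.191, adjusted p = 0.884 with an estimated correlation). Its median log2 change was 0.34. The fit shares its spread with the CD11c+ libraries, between which 22 of these 23 genes differed, so missing calls leave open a difference. Folr2 stood at 198 and 232 CPM in CD11b+CD11c+ replicates against 102 and 101 in CD11b+ replicates. Mrc1 stood at 2230 and 2760 against 1420 and 1560, while Cd14 overlapped (1080 and 1630 against 1280 and 1540). Pdcd1lg2 did not pass the test without CD11b+CD11c+ replicate 1 (log2 1.5) or CD11b+ replicate 2 (log2 1.71). Maf did not pass the test without CD11b+ replicate 2 (log2 0.64), CD11b+ replicate 1 (log2 0.55) or CD11b+CD11c+ replicate 2 (log2 0.34).

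Monocyte genes fell in 7 of 12 cases (camera adjusted p = 3e-05, adjusted p = 0.259 with an estimated correlation), led by Vcan, a matrix proteoglycan gene (6.47-fold, log2 -2.69 ± 0.12, adjusted p = 9.43e-05), and Chil3 (log2 -2.78 ± 0.23). Vcan was higher in CD11c+ replicates (25.4 and 27.9 CPM) than in CD11b+CD11c+ replicates (17.8 and 17.2). So was the stromal gene Col3a1 (724 and 794 against 465 and 391), unlike Chil3 (0.0395 and 0.185 against 6.46 and 4.89). Which cells Vcan came from was not tested. Neutrophil genes fell in 7 of 14 (camera adjusted p = 7.75e-11, adjusted p = 0.19 with an estimated correlation), with Retnlg at 27 ± 0.511 against 274 ± 29.3 CPM, and eosinophil genes in 4 of 9 with 1 higher (camera adjusted p = 5.21e-04, adjusted p = 0.259 with an estimated correlation), with Alox15 at log2 -3.19 ± 0.32 and Ccr3 at -3.42 ± 0.40. The neutrophil gene S100a8 was far less abundant than Retnlg in CD11b+ replicates (21 and 20.7 CPM). Stromal genes fell in 8 of 12 (camera adjusted p = 5.95e-07, adjusted p = 0.259 with an estimated correlation), with Sparc at log2 -2.23 ± 0.21 and Bgn at -2.48 ± 0.52. None of 15 epithelial genes was called, though the list stood lower (camera adjusted p = 8.69e-04, adjusted p = 0.44 with an estimated correlation). The B cell list also stood lower, with 1 of 15 genes called (camera adjusted p = 0.0079, adjusted p = 0.259 with an estimated correlation). So did the plasma cell list, with 2 of 11 (camera adjusted p = 0.0222, adjusted p = 0.567 with an estimated correlation), and the mast cell and basophil list, with 1 of 8 (camera adjusted p = 0.0407, adjusted p = 0.259 with an estimated correlation). Several mast cell and basophil genes lay near the floor. Mcpt2 had 0 counts in both groups, and Mcpt8 had 3 counts in CD11b+ and 0 in CD11b+CD11c+ cells. Other genes with the smallest p-values were Klri1 (7.2-fold), Ramp3, Pkib, Zfp366 and Olfm1 among those higher, and Nfe2, Pi16, Rab44, Asb2, Chst15, Syne1 and Cd300lf among those lower. Ccr3 had a log2 change of -4.04 without CD11b+CD11c+ replicate 2. Bgn did not pass the test without CD11b+CD11c+ replicate 1 (log2 -2.46), CD11b+ replicate 1 (log2 -2.34), CD11b+CD11c+ replicate 2 (log2 -2.50) or CD11b+ replicate 2 (log2 -2.61).

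Among genes of the sorting gate, Itgax had a log2 change of 0.56 ± 0.13 (adjusted p = 0.0258), with Itgam at 0.09 ± 0.19, H2-Ab1 at 0.78 ± 0.19, H2-Aa at 0.59 ± 0.18, Cd74 at 0.60 ± 0.19 and Ptprc at 0.02 ± 0.11; only Itgax and H2-Ab1 of these passed the test. There were 1099 genes higher and 717 lower in CD11b+CD11c+ cells (edgeR, 60.5% of calls higher). With DESeq2 size factors in the same fit the share higher was 49.6%, and the median change of all genes moved from 0.09 to 0.02 on the log2 scale. Leaving out single libraries gave 366 and 251 without CD11b+CD11c+ replicate 1, 537 and 288 without its replicate 2, 257 and 202 without CD11b+ replicate 1, and 377 and 342 without its replicate 2. Adjusted over the list alone, 8 general dendritic cell genes rose, 11 of mature dendritic cells with 1 lower, 10 of class II presentation and 15 of the cell cycle. By the same adjustment 9 neutrophil and 10 stromal genes fell, no macrophage gene passed, the tolerance list had 3 higher and 2 lower, 4 of the 6 gate genes rose, and the other lists named for this comparison kept their counts. Itgax did not pass the test without CD11b+CD11c+ replicate 1 (log2 0.66), CD11b+ replicate 1 (log2 0.47), CD11b+CD11c+ replicate 2 (log2 0.45) or CD11b+ replicate 2 (log2 0.66). H2-Ab1 did not pass the test without CD11b+CD11c+ replicate 1 (log2 0.83), CD11b+ replicate 1 (log2 0.55) or CD11b+CD11c+ replicate 2 (log2 0.73).

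The comparison of CD11b+CD11c+ with CD11c+ colonic cells sets side by side cells that share CD11c and were sorted apart by CD11b. Macrophage, lysosome, complement and chemokine genes and genes of cDC2 were higher in CD11b+CD11c+ cells, and genes of cDC1 and of lymphocytes were lower. All 23 macrophage genes rose (camera adjusted p = 2.6e-11, adjusted p = 0.302 with an estimated correlation), such as Maf (85.9 ± 19.6 against 6.92 ± 0.0955 CPM, log2 3.63 ± 0.18) and Cd163 (log2 5.70 ± 0.43). Of 18 lysosome genes 17 rose (camera adjusted p = 5.78e-10, adjusted p = 0.302 with an estimated correlation), with Ctsd 9.77-fold and Lamp2 3.78-fold higher, as did all 13 complement genes (camera adjusted p = 1.99e-07, adjusted p = 0.302 with an estimated correlation), with Cfp, the gene for properdin, at log2 2.29 ± 0.10 and Itgam 23.9-fold higher. Chemokine genes rose in 16 of 19 and fell in 1 (camera adjusted p = 1.04e-06, adjusted p = 0.302 with an estimated correlation), with Ccl6 13.5-fold higher and Ccl24 at 39.6 ± 6.52 against 0.185 ± 0.262 CPM, with no count in CD11c+ replicate 1. Inflammatory cytokine genes rose in 11 of 16 (camera adjusted p = 2.22e-04, adjusted p = 0.302 with an estimated correlation), with Tnfsf9 at log2 3.06 ± 0.16 and Il6 at 2.82 ± 0.24. Cd163 had log2 changes of 4.99 without CD11c+ replicate 1 and 6.63 without CD11c+ replicate 2.

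Of 10 cDC2 genes 8 rose and 1 fell (camera adjusted p = 1.04e-04, adjusted p = 0.302 with an estimated correlation). Clec10a stood at 106 ± 12.5 against 6.26 ± 1.03 CPM (17-fold, adjusted p = 4.45e-06) and Cd209a at 200 ± 23.7 against 8.56 ± 2.39 (23.6-fold). Genes of mature dendritic cells rose in 9 of 15 (camera adjusted p = 4.04e-04, adjusted p = 0.302 with an estimated correlation), with Cd40 7.43-fold, Il4i1 4.65-fold and Ccr7 4.3-fold higher. In the tolerance list 7 of 16 rose and 1 fell (camera adjusted p = 0.0241, adjusted p = 0.302 with an estimated correlation), with Ebi3, a subunit of regulatory cytokines, 3.33-fold, Tgfb1 2.75-fold and Aldh1a2 3.24-fold higher. Immediate early and stress genes rose in 14 of 18 (camera adjusted p = 4.14e-06, adjusted p = 0.302 with an estimated correlation), with Egr2 at log2 3.24 ± 0.18 and Ier3 at 3.98 ± 0.36. Class II presentation genes rose in 1 of 11 cases and fell in 2, and the list was not called (camera adjusted p = 0.64, adjusted p = 0.842 with an estimated correlation), with Ctss, a protease of class II processing, at log2 1.72 ± 0.21 and H2-Ob at -1.17 ± 0.20. Ier3 had log2 changes of 3.36 without CD11c+ replicate 1 and 4.69 without CD11c+ replicate 2.

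Of 12 cDC1 genes 11 fell (camera adjusted p = 2.65e-07, adjusted p = 0.302 with an estimated correlation), with Ppt1 4.71-fold, Tlr3 3.98-fold and Irf8 2.9-fold lower. Cell cycle genes fell in 9 of 15 and rose in 1 (camera adjusted p = 0.00212, adjusted p = 0.302 with an estimated correlation), with Mcm6 at log2 -0.74 ± 0.09 and Rrm2 at -1.24 ± 0.17. Among other cell types, T cell genes fell in 12 of 14 with 1 higher (camera adjusted p = 1.27e-05, adjusted p = 0.302 with an estimated correlation), NK cell and innate lymphoid genes in 11 of 14 with 1 higher (camera adjusted p = 2.73e-04, adjusted p = 0.302 with an estimated correlation) and plasma cell genes in 9 of 11 with 1 higher (camera adjusted p = 5.34e-04, adjusted p = 0.302 with an estimated correlation). Lck stood at log2 -4.23 ± 0.60 (140 and 54.1 CPM in CD11c+ replicates 1 and 2), Klrb1c at -4.35 ± 0.54 and Txndc5 at -1.16 ± 0.12. Neutrophil genes rose in 8 of 14 (camera adjusted p = 4.04e-04, adjusted p = 0.302 with an estimated correlation). Besides genes already named, the smallest p-values included those of Gda (24.4-fold), Pltp, Bank1 and Retnla (234-fold), all higher, and those of Rnase6, Gramd3, Tcf7 (15.9-fold), Bcl2l14, Tlr11, Elac2 and Itga3, all lower. Lck had log2 changes of -3.50 without CD11c+ replicate 1, -5.62 without CD11b+CD11c+ replicate 1 and -3.58 without CD11b+CD11c+ replicate 2. Klrb1c had log2 changes of -5.90 without CD11b+CD11c+ replicate 1 and -3.68 without CD11b+CD11c+ replicate 2.

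For the gate, Itgax had a log2 change of -0.17 ± 0.13 (adjusted p = 0.331), with H2-Ab1 at -0.01 ± 0.19, H2-Aa at 0.13 ± 0.18, Cd74 at 0.25 ± 0.19 and Ptprc at 0.00 ± 0.11; none of these passed the test. In total 3210 genes were higher and 2567 lower (edgeR, 15074 tested). Without CD11c+ replicate 1 there were 2080 higher, and without CD11b+CD11c+ replicate 2 there were 1328 lower. Adjusted over the list alone, 8 tolerance, 16 stress, 10 cell cycle genes falling and 2 NK cell genes rising passed, and the other lists named for this comparison kept their counts.

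**Figure D3:**
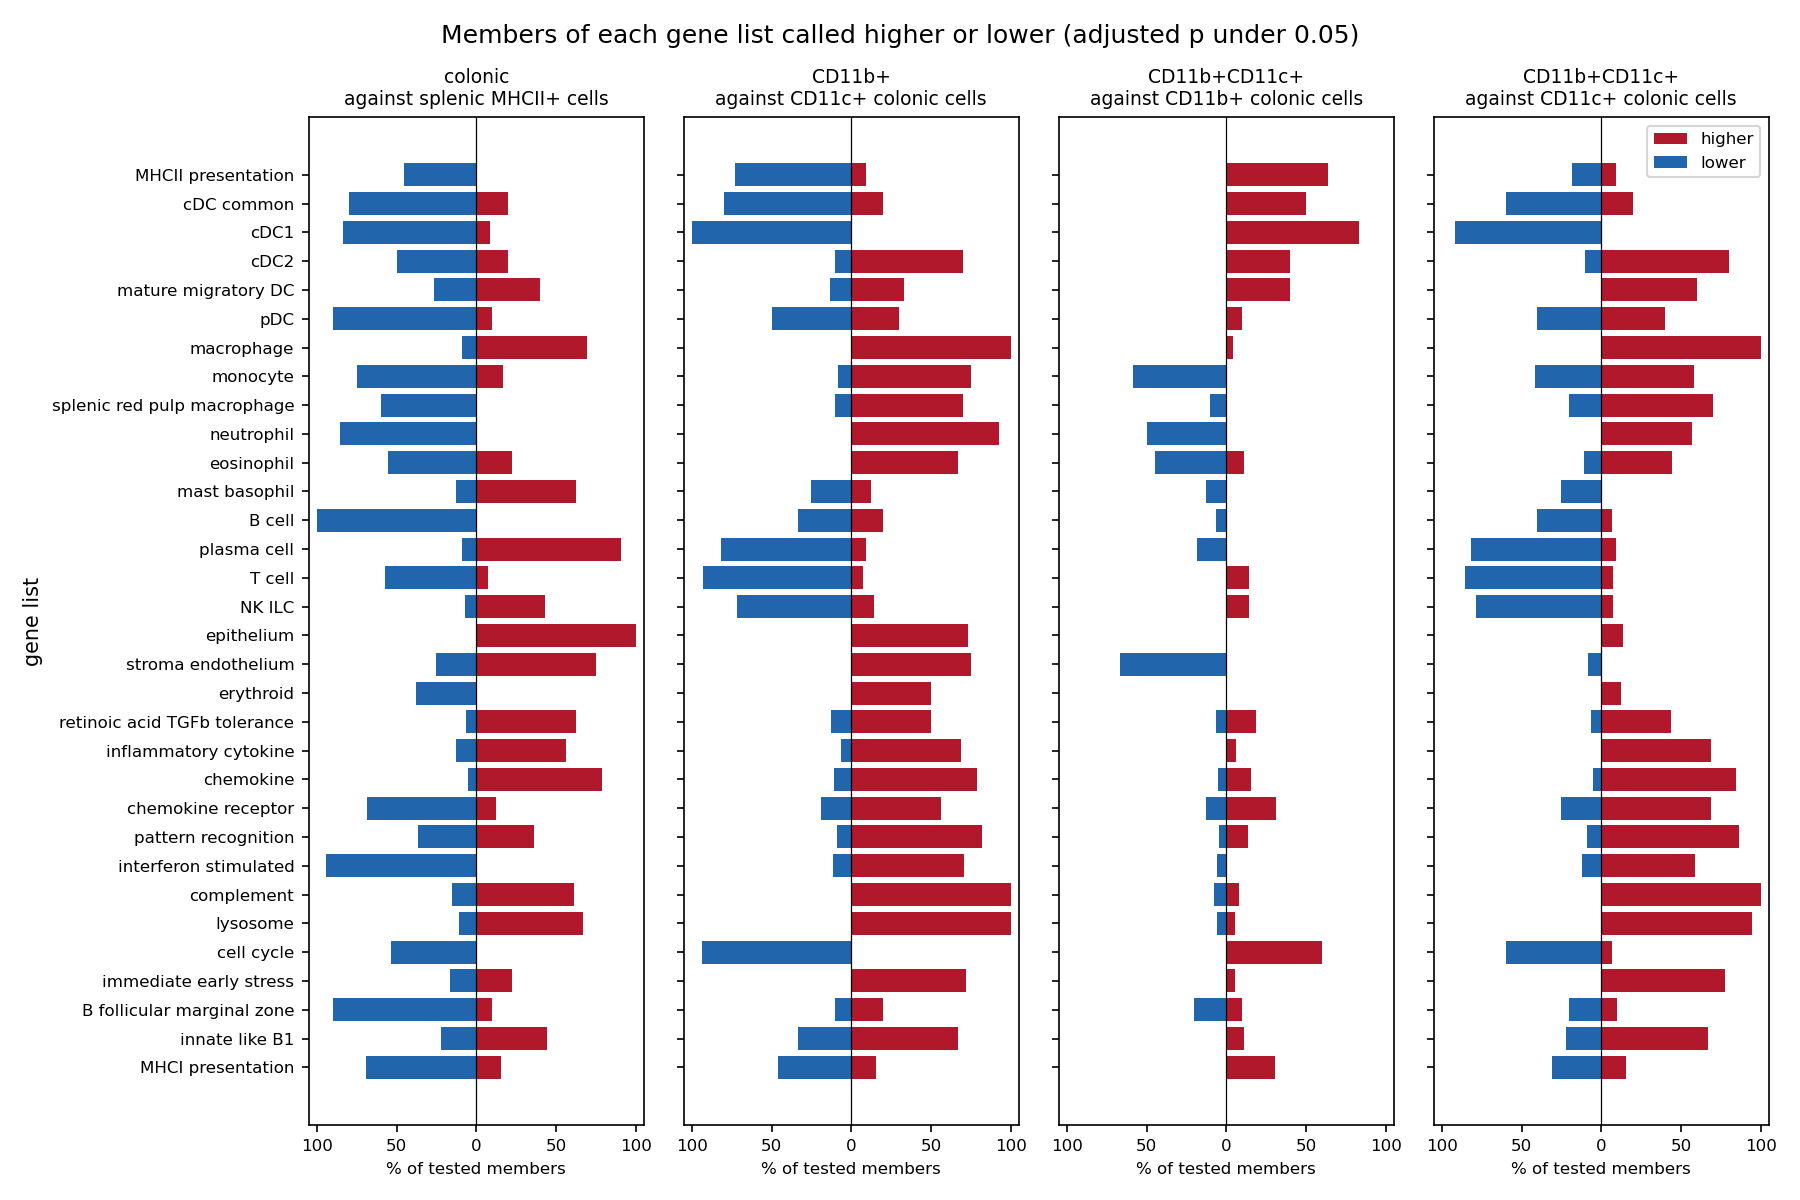
Share of each gene list's tested members called higher (red, to the right) or lower (blue, to the left) in the 4 comparisons, in percent, at an adjusted p under 0.05 by edgeR. Macrophage, lysosome and complement genes extend far to the right in both comparisons with CD11c+ cells, and epithelial genes reach 15 of 15 in the colonic against splenic comparison.

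Signature genes of a colonic subset were those higher than in both other subsets. CD11c+ cells had 1284 signature genes, CD11b+ cells 199 and CD11b+CD11c+ cells 81, of which 538, 152 and 30 stood at least 2-fold above both. Genes of other cell types were among them. The CD11c+ signature held 11 listed cDC1 genes, 12 of T cells, 10 of NK and innate lymphoid cells and 6 of plasma cells. In the CD11b+ signature were 6 listed neutrophil, 4 eosinophil, 4 monocyte and 0 macrophage genes. The CD11b+CD11c+ signature held 5 genes of mature dendritic cells and 3 of cDC2. The CD11c+ signature was led by Ppt1, a lysosomal thioesterase gene, Rnase6, Tcf7, a transcription factor gene of lymphocytes, Bcl2l14, Gramd3, Tlr11, Elac2 and Itga3. Ppt1 stood at 726 ± 4.53 CPM against 154 ± 22.4 and 100 ± 5.65, and Tcf7 at 39.3 ± 10.2 against 2.46 ± 0.683 and 2.66 ± 0.355. The CD11b+ signature was led by Nfe2, Vcan, Pi16, Rab44, Syne1, Chst15, Cd300lf and Padi4, an arginine deiminase gene of granulocytes. Rab44 stood at 575 ± 70.5 CPM in CD11b+, 51.7 ± 10.4 in CD11b+CD11c+ and 0.377 ± 0.253 in CD11c+ cells, and Padi4 at 86.3 ± 1.36, 7.53 ± 3.06 and 0.425 ± 0.0981. The CD11b+CD11c+ signature was led by the lectin genes Cd209a and Cd209c, the lysozyme gene Lyz1, Myo1g, Tnip3, Slc41a1, Siglecg and Hr. Cd209a stood at 200 ± 23.7 CPM against 39.9 ± 4.33 in CD11b+ and 8.56 ± 2.39 in CD11c+ cells, and Tnip3, an inhibitor of NF-kappa-B signalling, at 242 ± 5.57 against 88 ± 1.9 and 29.9 ± 6.4. The CD11b+CD11c+ signature had 0 genes without CD11b+ replicate 1, without CD11b+ replicate 2 or without CD11b+CD11c+ replicate 1, and 22 without CD11b+CD11c+ replicate 2 (edgeR), against 946 genes at an unadjusted p under 0.05 and, with all subset libraries, 173 by DESeq2's Wald test, 0 by limma at both pseudocounts, 49 with DESeq2 size factors, 23 with a length offset and 0 by edgeR in the subsets alone. Without either splenic library it had 47. The CD11b+ signature had 41 and 84 genes without CD11b+ replicates 1 and 2, 57 and 71 without CD11b+CD11c+ replicates 1 and 2, and 327 without either splenic library. The CD11c+ signature had 752 and 659 genes without CD11b+ replicates 1 and 2, and 819 and 424 without CD11b+CD11c+ replicates 1 and 2.

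Genes higher in colonic than in splenic MHCII+ cells were then sought among the subset signatures. These signatures compare other libraries, but both sets of calls come from 1 fit that shares its filter, scaling and spread over all 10 libraries. They held 101 of the 199 CD11b+ signature genes where 66.1 were expected (odds ratio 2.09, Fisher's exact test, two-sided, adjusted p = 4.49e-07) and 45 of the 81 CD11b+CD11c+ genes where 26.9 were expected (odds ratio 2.52, adjusted p = 4.27e-05). They held 263 of the 1284 CD11c+ genes where 427 were expected (odds ratio 0.491, adjusted p = 2.38e-25). Genes are not independent replicates, so these p-values are descriptive. The CD11b+ odds ratio was 1.23 without CD11b+ replicate 1 (adjusted p = 0.762) and 4.74 and 5.84 without splenic replicates 1 and 2. It was 3.56 with no filter, 4.72 with limma on log2(TPM + 1) and 4.52 with each comparison's own libraries alone. The CD11b+CD11c+ odds ratio lost its call without CD11b+CD11c+ replicate 2 (2.05, adjusted p = 0.11) and with a length offset (1.31, adjusted p = 0.5). Of the 12 stromal and endothelial genes, 9 were higher in colonic than in splenic cells, 9 in CD11b+ than in CD11c+ cells and 8 in CD11b+ than in CD11b+CD11c+ cells, and 1 was among the CD11b+ signature genes. In the CD11c+ signature, 0 of 12 T cell, 2 of 10 NK and innate lymphoid and 6 of 6 plasma cell genes were also higher in colonic MHCII+ cells. In the CD11b+ signature, 0 of 6 neutrophil, 2 of 4 eosinophil and 1 of 4 monocyte genes were.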

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

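No group held enough libraries for a test of outlying samples, and no contrast was repeated in another tissue or age. The 1013 transcripts with no gene in the annotation used took up to 0.912% of a library's estimated counts, in colonic MHCII+ replicate 1, which is above the level that a count of 0 allows, and they enter no comparison.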

How the results depend on the processing

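Fits without immunoglobulin and mitochondrial genes and the overlap among genes of at least 10 mean CPM were chosen after the data were seen, and the other alternatives before. The counts of genes higher and lower in colonic MHCII+ cells stayed within 1.5 times of 5010 and 4633 under all alternatives. The counts of gene lists called stayed within 1.5 times in the 4 comparisons under the alternatives run for them, which leave out DESeq2's Wald test and limma. In CD11b+ against CD11c+ cells the genes lower (3616) were 2384 and 2331 with limma on log2(TPM + 1) and log2(TPM + 0.1), and leaving out libraries gave 2429 to 3176 higher and 2438 to 3249 lower. In CD11b+CD11c+ against CD11b+ cells the genes higher (1099) were 731 with DESeq2 size factors, 336 and 314 with limma at both pseudocounts, 546 with a length offset and 536 in the colonic subsets alone, and 257 to 537 with libraries left out. The genes lower (717) were 437 with a length offset and 202 to 342 with libraries left out. In CD11b+CD11c+ against CD11c+ cells leaving out libraries gave 2080 to 2884 higher and 1328 to 2300 lower. The CD11b+ signature (199) held 301 genes with no filter, 474 by DESeq2's Wald test, 304 and 124 with limma, 90 with a length offset and 370 in the subsets alone, and 41 to 327 with libraries left out. The CD11b+CD11c+ signature (81) held 49 with DESeq2 size factors, 173 by DESeq2's Wald test, 0 and 0 with limma, 23 with a length offset and 0 in the subsets alone by edgeR, and 0 to 116 with libraries left out, against 946 genes at an unadjusted p under 0.05. The CD11c+ signature (1284) held 680 and 596 with limma and 679 with a length offset, and 424 to 1300 with libraries left out. The overlap odds ratio was 1.31 (adjusted p = 0.5, Fisher's exact test) for CD11b+CD11c+ genes with a length offset. For CD11b+ genes (2.09) it was 3.56 with no filter, 4.72 with limma on log2(TPM + 1) and 4.52 with each comparison's own libraries alone, each with the call kept. With libraries left out it was 1.23 to 5.84 for CD11b+, 2.05 to 2.49 for CD11b+CD11c+ and 0.438 to 0.61 for CD11c+ genes, with no value where the signature was empty. Leaving out a library leaves fewer samples, though some counts and odds ratios rose on leaving one out. The cause of the moves was not tested for any alternative. The labels do not say that equal numbers pair the subset libraries, and replicate differences correlated at 0, -0.05 and 0.23 over genes. Over V segments, those of CD11b+ cells correlated at -0.31 and -0.35 with the other subsets, so the block may pair the CD11b+ libraries wrongly. With a replicate block the 3 subset comparisons gave 3631 and 3569, 1184 and 681, and 3155 and 2509 genes higher and lower, and signatures of 161, 80 and 1275 genes, with 24, 17 and 20 lists called. Of 6444 values of named genes under the alternatives, 6156 kept their side of the threshold, 273 lost the call and 15 gained one. Among values called in the main fit or in the alternative, 0 turned direction. The direction of values called in neither fit was not compared.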

Other observations

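The tests below were chosen after the results were seen, except the test of same-numbered subset libraries over all 3 pairs, which was fixed before its correlations were computed. The bounds of the tests on cDC1, macrophage and epithelial genes were set after their values were seen, and those on macrophage genes and on carry-over replaced earlier tests, of which 2 had left an explanation open. Other gene groups moved too. In colonic against splenic MHCII+ cells, 9 of 10 plasmacytoid dendritic cell genes fell and 1 rose (camera adjusted p = 0.0203, adjusted p = 0.387 with an estimated correlation), and 9 of 10 genes of follicular and marginal zone B cells fell and 1 rose (camera adjusted p = 0.00151, adjusted p = 0.218 with an estimated correlation). Chemokine receptor genes fell in 11 of 16 and rose in 2 (camera adjusted p = 0.0433, adjusted p = 0.428 with an estimated correlation), and class I presentation genes fell in 9 of 13 and rose in 2 (camera adjusted p = 0.0294, adjusted p = 0.428 with an estimated correlation). Monocyte genes fell in 9 of 12 and rose in 2 (camera adjusted p = 0.00616, adjusted p = 0.526 with an estimated correlation), and cell cycle genes fell in 8 of 15 (camera adjusted p = 0.0276, adjusted p = 0.55 with an estimated correlation). Mast cell and basophil genes were higher in 5 of 8 and lower in 1 (camera adjusted p = 0.211, adjusted p = 0.581 with an estimated correlation), and erythroid genes were lower in 3 of 8 (camera adjusted p = 0.339, adjusted p = 0.692 with an estimated correlation). The mast cell genes Mcpt1 and Mcpt2 had 0 counts in splenic MHCII+ cells. Complement genes rose in 8 of 13 and fell in 2 (camera adjusted p = 0.211, adjusted p = 0.692 with an estimated correlation), and genes of mature dendritic cells rose in 6 of 15 and fell in 4 (camera adjusted p = 0.252, adjusted p = 0.582 with an estimated correlation). The cDC2 list had 2 higher and 5 lower of 10 (camera adjusted p = 0.124, adjusted p = 0.581 with an estimated correlation), and the eosinophil list 2 higher and 5 lower of 9 (camera adjusted p = 0.211, adjusted p = 0.599 with an estimated correlation). Pattern recognition genes went both ways, 8 higher and 8 lower of 22 (camera adjusted p = 0.612, adjusted p = 0.867 with an estimated correlation). So did stress genes, 4 higher and 3 lower of 18 (camera adjusted p = 0.589, adjusted p = 0.867 with an estimated correlation), and innate-like B cell genes, 4 higher and 2 lower of 9 (camera adjusted p = 0.532, adjusted p = 0.692 with an estimated correlation). Adjusted over the list alone, the cDC2 list had 6 lower and the stress list 3 higher and 2 lower, and the other counts of this paragraph were the same. Immunoglobulin constant region genes differed: Ighm stood at 198 ± 47.3 CPM in colonic and 1860 ± 105 in splenic cells, Ighd at 5.3 ± 0.194 and 175 ± 21.2, and the kappa light chain gene Igkc at 3820 ± 155 and 403 ± 39.6.

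Genes of splenic red pulp macrophages, lower in colonic than in splenic MHCII+ cells in 6 of 10 cases, were higher in CD11b+ than in CD11c+ cells in 7 of 10 cases and lower in 1 (camera adjusted p = 0.00278, adjusted p = 0.335 with an estimated correlation). They were also higher in CD11b+CD11c+ than in CD11c+ cells in 7 and lower in 2 (camera adjusted p = 0.00372, adjusted p = 0.302 with an estimated correlation). Pattern recognition genes rose in 19 of 22 and fell in 2 in CD11b+CD11c+ against CD11c+ cells (camera adjusted p = 9.75e-07, adjusted p = 0.302 with an estimated correlation). Class I presentation genes rose in 4 of 13 in CD11b+CD11c+ against CD11b+ cells (camera adjusted p = 5.69e-04, adjusted p = 0.19 with an estimated correlation), and adjusted over the list alone in 5. Genes of innate-like B cells, several of which myeloid cells also express, rose in 6 of 9 in CD11b+CD11c+ against CD11c+ cells, with 2 lower (camera adjusted p = 0.0241, adjusted p = 0.302 with an estimated correlation), and adjusted over the list alone in 7.

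Immunoglobulin V segments differed between replicate libraries of the colonic subsets; 159 of 218, those with a mean of at least 50 counts, were compared. Shared plasma cell RNA in same-numbered libraries was to be kept if replicate differences correlated over 0.5 in all 3 pairs of subsets and set aside if the largest was under 0.2, and neither bound was met, since the largest was 0.52 and the others -0.31 and -0.35. Taken apart afterwards, the pairs with CD11b+ libraries (at most -0.31) argue against it, and the pair of CD11c+ and CD11b+CD11c+ cells (0.52) leaves it open. V segment profiles of CD11b+ replicate 1 and replicates 2 of the other subsets correlated at 0.86 to 0.88, those of CD11c+ and CD11b+CD11c+ replicates 1 at 0.81 and other pairs of subset libraries at 0.63 to 0.71, but the 3 libraries were grouped because of these values, so 1 source of plasma cell RNA in them is untested and cannot be told apart. Carry-over of CD11c+ replicate 2 material into CD11b+ replicate 1 brings all transcripts at 1 share. The 25th percentile of 12 cDC1 genes (1.78% of their CD11c+ replicate 2 level, median 10.3%) limits it to 4.43% of the Igha of CD11b+ replicate 1 (25.7% at the median). The value at the 25th percentile argues against carry-over as the main source. The median lies just over the bound for setting carry-over aside, and both the percentile and the bound were chosen after the values were seen. No biological explanation was tested.

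Macrophage genes differed between the CD11c+ libraries, with 22 of 23 higher in replicate 2 and a median log2 ratio of 2.29, and 12 of 14 T cell genes and 13 of 14 NK cell and innate lymphoid genes were lower there (medians of -1.33 and -0.77). A share of CD11b+ cell RNA in replicate 2 large enough for the median macrophage gene (12.6%) would bring all abundant transcripts of these cells. Of 1984 genes with at least 100 CPM in both CD11b+ libraries, 21 stayed under 0.5 times the level needed, such as Retnlg (0.185 CPM in replicate 2 against 274 ± 29.3 in CD11b+ cells) and Alox15 (0.309 against 256 ± 10.8), which argues against it. For CD11b+CD11c+ cell RNA (9.66%), 12 of 2142 genes did, such as Retnla (0.988 against 227 ± 53.7) and Fcna (3.27 CPM against a needed level of 21.1). Cd163 (20.7 against 715 ± 58.3) did too, but it belongs to the macrophage genes that set the share. The genes outside that list argue against that source as well. RNA of part of these cells, such as macrophages alone, and a difference in the sorted cells stay open, and no biological explanation was tested.

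Epithelial genes were high in the colonic MHCII+ libraries, at 4.6, 6.64 and 10.7 times the level in CD11b+, CD11b+CD11c+ and CD11c+ cells (medians of 15 genes). Epithelial RNA of 1 source in all colonic libraries would keep the ratios between these genes, and the SD of their log2 ratios was at most 0.61, under the bound of 0.75. Macrophage genes gave 0.5, 0.68 and 0.65 by the same measure and also stayed under this bound, so the test does not separate sources, and such RNA cannot be told apart from cells that differ between the sorts. That difference between sorted populations stays open and was not tested. The colonic MHCII+ and the subset libraries also belong to separate numbered sets, so a difference between the sets cannot be told apart from either.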
